A study of Homo sapiens with 12 samples.

How the data were processed

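Gene expression was measured in 12 RNA samples of established human cell lines, 1 Illumina BeadChip array per sample. The lines were HEK001, a keratinocyte line, and HEK293, an embryonic kidney line. Cells of each line carried a lentiviral short hairpin against NCSTN, the gene of the gamma-secretase subunit nicastrin, or a pLKO control hairpin against luciferase. Per the labels, virus was removed after 24 h, polybrene was used at 10 µg/mL, and selection with puromycin lasted about 2 weeks. Puromycin was given at 2 µg/mL to HEK293, and at a labelled 0.5 to HEK001 with an incompletely written unit. Labelled RNA was made from 100 ng of total RNA. A single NCSTN hairpin was used, with the target sequence GCTCTACTGAATACTCTACAT. Its position was not analysed here because no genome or transcript sequences were used, and the test of genes matching the seed of the hairpin that was planned for the same purpose was not run.

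The 4 groups of 3 arrays were taken from the sample titles, which give the line and the hairpin. The source name in the labels gives HEK001 for all 12 samples, while the titles and the cell line entries give HEK293 for 6 of them. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

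The deposited scanner table holds, per the file headers, a mean signal, a detection p-value, a bead count and a bead error for each of 47318 probes on each array. The authors' deposited signal is a linear intensity from which background had been subtracted, since between 27.07% and 29.12% of the values per array lie below 0. It was not normalized between arrays. The deposited detection p-values fall in steps of 1 over 770. The 12 columns of bead errors were not used here. The authors' second deposited table holds log2 values of 21270 probes. Its columns share a median of 6.666 and a minimum of 1, its ranks equal those of the same array's signals, and it keeps the probes with a detection p-value under 0.05 on at least 4 of 12 arrays, which held for all 47318 probes when tested on the values. The submitters' processing notes name GenomeStudio 2010 and R 3.0.2 without saying which step used them.

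Signals were corrected for background by normexp with parameters inferred from the detection p-values, given an offset of 16 and quantile normalized on the log2 scale, as limma's neqc does. Probes with a detection p-value under 0.01 on at least 3 of the 12 arrays were kept, which left 18152 probes. Gene names came from the platform annotation, which gives 1 gene for 16040 probes, several for 3 and none here for 31275. Symbols were checked by gene identifier against RefSeq genes of GRCh38.p14, used for names alone, which held 16030 of the 16040 probes. Of the kept probes, 14411 had a single gene and 3741 were unnamed and left out. The probe with the highest mean stood for each gene, which gave 11075 genes. Among 2729 genes with several kept probes, probes were called in opposite directions for 2 genes in HEK001 (CYTH2 and NGDN) and 6 in HEK293.

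A linear model with a mean for each of the 4 groups was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, 8 residual and 12.8 total degrees of freedom and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this limma fit. The contrasts were the NCSTN hairpin against the control hairpin in each line, the difference between those effects, and HEK293 against HEK001 in the control cells. The 2 knockdown contrasts share no arrays, but both use the same estimate of each gene's spread. Where a probe was detected on fewer than all 3 arrays of the dimmer group, only a lower bound of the fold is given, computed against the higher of its own value and the lowest value among detected probes of each array. Where it was detected in neither group, no change is stated. List counts, list means and differences between the lines use the fitted values.

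Before the data were examined, 26 gene lists were fixed, namely gamma-secretase subunits and substrates, Notch receptors and Notch targets, interferon-stimulated genes, MHC class I presentation, inflammatory and antimicrobial genes, basal and differentiation markers of keratinocytes, genes typical of HEK293, fibroblast, melanocyte and leukocyte markers, replication, mitosis, p53 targets, unfolded protein response, cholesterol and fatty acid synthesis, lysosome, hypoxia, immediate early genes, metallopeptidases, TGF-beta targets, Wnt targets and reference genes. Of the 26, 25 had at least 4 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The named genes were chosen by a rule fixed at the same time. It takes every gamma-secretase subunit, and in each line the 10 genes with the highest and the 10 with the lowest log2 difference among called genes whose arms did not overlap and whose brighter arm was detected on all 3 arrays. It also takes the 10 genes called in both lines with the same sign and up to 6 with opposite sign, ranked by the smaller of the absolute differences, the 6 with the largest difference between the lines, and 6 in each direction between the control lines. It takes up to 4 members of the interferon and Notch target lists, and up to 3 of any other list that passed its test or had at least 3 called members, of which 2 were taken. Unnamed loci, probes with several genes and Y-linked genes were left out.

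The procedure was tested on simulated data for the HEK001 knockdown contrast with 11075 genes. It recovered 79.1% of 67 genes changed 1.5-fold, 95.52% of 67 changed 2-fold and 96.97% of 66 changed 4-fold. The changed genes were drawn only from brighter genes, and the simulated noise was independent between genes. Recovery of dim genes was therefore not tested. It made 17 false calls among 10875 unchanged genes, which was 8.586% of its calls and above the nominal rate.

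Between 14818 and 16333 probes were detected per array (31.32% to 34.52%), and the median number of beads per probe was 22 on every array. The number of arrays limits the precision. The median standard error of a knockdown effect was 0.126 on the log2 scale. The alternatives tried were another offset, no background correction, median scaling, the authors' values, no filter or a stricter filter on dim probes, each line alone, the replicate number as a block, an intensity trend with robust variance, array weights, every probe on its own, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.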

Results

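The series asks which transcripts change when nicastrin, the substrate-binding subunit of the gamma-secretase complex, is knocked down in 2 human cell lines. Expression was measured on 12 arrays: HEK001 keratinocytes and HEK293 embryonic kidney cells, each with the NCSTN hairpin or the luciferase control hairpin, 3 arrays per group. Between 14818 and 16333 of the 47318 probes were detected per array. Replicates of a group correlated across genes at Pearson's r between 0.9895 and 0.9943, arrays of the other arm of the line at 0.9758 to 0.9867, and arrays of the other line at 0.7692 to 0.7942. Differences are given as log2 of the NCSTN hairpin minus the control hairpin with the standard error of the fit. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples.

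NCSTN itself was lower on every array with its hairpin than on every control array of the same line. In HEK001 it fell by 3.09 (SE 0.116, adjusted p = 1.39e-08), which left 11.8% of the control level (95% interval of the fit 9.9% to 14%). In HEK293 it fell by 1.97 (SE 0.116, adjusted p = 2.38e-07), which left 25.5% (21.5% to 30.4%). The knockdown was deeper in HEK001, with a difference of 1.12 between the lines (adjusted p = 0.00047). The values rest on 1 probe, detected on all 12 arrays. The other subunits measured, PSEN2, APH1A, APH1B and PSENEN, did not pass the threshold in either line. Their log2 differences were −0.17, −0.04, 0.29 and −0.06 in HEK001 and 0.09, 0.23, 0.22 and 0.23 in HEK293.

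**Figure D1:**
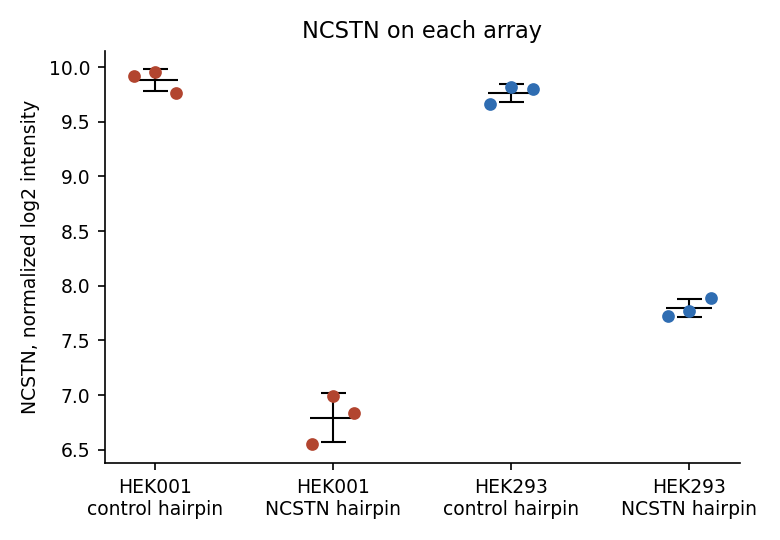
Normalized log2 intensity of the NCSTN probe on each array (points) in the 4 groups, with the group mean and SD (bars, n = 3). The knockdown arrays lie between 6.55 and 6.99 in HEK001 and between 7.73 and 7.89 in HEK293, below the control arrays of their line.

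The identity of the lines was examined in the control cells, because the labels conflict on it. The keratins KRT5, KRT14 and KRT6C were abundant in HEK001 and were detected on no HEK293 control array. KRT5 was at least 301-fold higher in HEK001, KRT14 at least 247-fold and KRT6C at least 356-fold, as were TGFBI (at least 414-fold), FST (at least 268-fold) and LAD1 (at least 168-fold). In HEK293, the tubulin gene TUBB2B was at least 102-fold higher, ZCCHC12 at least 59.8-fold, ID2 at least 57.9-fold, CYFIP2 at least 38-fold and LIN28B, a repressor of let-7 maturation, at least 35.4-fold. SNAR-A1, a small noncoding RNA with near-identical copies, was 6.14 higher on the log2 scale (SE 0.127). These single genes were picked for the largest differences in this same contrast. All 10 measured basal keratinocyte markers were lower in HEK293 (mean log2 difference −6.01, camera adjusted p = 1.43e-08, adjusted p = 0.013 with an estimated correlation). The fixed list of genes typical of HEK293 did not separate the lines. Of its 6 measured genes, 3 were higher and 3 lower in HEK293 (mean 1.52, camera adjusted p = 0.758). Of 42 interferon-stimulated genes, 37 were lower in HEK293 control cells and 4 higher (mean −1.83, camera adjusted p = 1.32e-08, adjusted p = 0.00195 with an estimated correlation). Of 9 Notch target genes, 7 were higher in HEK293 and 1 lower (mean 1.99, camera adjusted p = 0.00645, adjusted p = 0.0449 with an estimated correlation). Of 11075 genes, 8046 differed between the control lines (limma, adjusted p under 0.05), 4366 higher and 3680 lower in HEK293.

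In HEK001, knockdown cells had higher levels of FGFR3, a fibroblast growth factor receptor, of interferon-stimulated and MHC class I genes, and of keratinocyte markers, and lower levels of mitotic genes. FGFR3 rose by 2.57 (SE 0.104), the chemokine CXCL14 by 2.41 (SE 0.147), CLCA2 by 2.34 (SE 0.137) and the calprotectin subunit S100A8 by 1.80 (SE 0.109), and DIRC3 was at least 3.68-fold higher. IGFBP2, SAMD9, HLA-B and FOLR3 rose by between 1.56 and 1.79, and the alarmin IL33 was at least 2.23-fold higher, from a probe kept only with all 3 knockdown arrays. A second FGFR3 probe did not pass the threshold (log2 −0.27, adjusted p = 0.356 over all probes). Besides NCSTN, KRT80 fell by 1.96 (SE 0.128), TMEM156 by 1.54 (SE 0.0985), AUNIP by 1.48, MNS1 by 1.46, the histone variant H2AZ1 by 1.43, APIP by 1.41, NTM by 1.39 (−0.81 for a second probe) and the clock gene PER2 by 1.36. FAM43B was at least 2.04-fold lower. In all, 1799 of 11075 genes changed (limma, adjusted p under 0.05), 925 higher and 874 lower, and 109 of them by at least 2-fold, 68 higher and 41 lower. Without HEK001 control replicate 3 the count was 1146. The balance of directions depended on the processing, with 649 higher and 704 lower without background correction and 971 higher and 701 lower with median scaling. Without background correction, DIRC3, S100A8, FOLR3, KRT80, FAM43B and NTM kept their sign and did not pass the threshold. All of these but FAM43B were not detected in HEK293, whose arrays also enter the shared estimate of spread. Whether that cost them the call was not tested.

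Interferon-stimulated genes rose together in HEK001. Of 50 listed, 42 were measured, of which 30 were higher, 1 was lower and 11 did not pass the threshold, and 35 were higher and 2 lower when adjusted over the list alone. The mean log2 difference was 0.71 (camera adjusted p = 2.41e-20, adjusted p = 7.95e-05 with an estimated correlation). SAMD9 rose by 1.67 (SE 0.203), the antiviral effectors IFIT1 and MX2 each by 1.52, and the ubiquitin-like ISG15 by 1.32. Of 15 measured genes of MHC class I antigen presentation, 9 were higher and none was lower, also when adjusted over the list alone (mean 0.507, camera adjusted p = 1.48e-06, adjusted p = 0.00467 with an estimated correlation). HLA-B rose by 1.64 and HLA-C by 1.07, and whether their probes also read related HLA genes was not analysed here.

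Keratinocyte genes and proliferation genes moved in opposite directions in HEK001. Of 10 basal keratinocyte markers, 6 were higher (7 when adjusted over the list alone), with KRT15 up by 1.36 and DST, which anchors keratins to hemidesmosomes, up by 0.76. The mean was 0.475 (camera adjusted p = 4.47e-05, adjusted p = 0.027 with an estimated correlation). Of 14 differentiation markers 5 were higher, also when adjusted over the list alone (mean 0.335, camera adjusted p = 0.000714, adjusted p = 0.021 with an estimated correlation), among them SPRR1B (0.94) and DSG3 (0.84). Of 20 genes of G2/M and mitosis, 16 were lower (18 when adjusted over the list alone), with TOP2A, a topoisomerase, down by 1.00 and the cyclin CCNA2 down by 0.79. Their mean was −0.556 (camera adjusted p = 6.53e-14, adjusted p = 0.00163 with an estimated correlation). Of 19 genes of DNA replication, 12 were lower and 1, E2F1, was at least 1.42-fold higher (15 and 1 when adjusted over the list alone). TYMS, the thymidylate synthase gene, fell by 0.86. The mean was −0.351 (camera adjusted p = 4.13e-07, adjusted p = 0.0616 with an estimated correlation). Without background correction KRT15, DST, SPRR1B, DSG3 and E2F1 did not pass the threshold, DST and DSG3 did not with the authors' values, and the other probes of DST did not pass it either.

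Genes of cholesterol and fatty acid synthesis also rose in HEK001, where 8 of 20 were higher and 1 lower (12 and 1 when adjusted over the list alone). LSS rose by 0.67 and MVD by 0.58, and MVD in HEK001 did not pass without background correction or without any 1 HEK001 array other than knockdown replicate 2 (0.51 to 0.65). The mean was 0.26 (camera adjusted p = 0.000414, adjusted p = 0.0176 with an estimated correlation). The call was lost with an estimated correlation for the lysosome list (mean 0.233, 5 of 16 higher, also when adjusted over the list alone, GAA 0.78 and CTSD 0.71, camera adjusted p = 0.0111, adjusted p = 0.298). It was also lost for TGF-beta targets (mean −0.308, 4 of 12 lower, also when adjusted over the list alone, CCN2 −1.12 and PMEPA1 −1.03, with −0.50 and −0.79 for its other probes, camera adjusted p = 0.0111, adjusted p = 0.171). A second CCN2 probe did not pass the threshold (log2 −0.76). Genes typical of HEK293 lost the call too (mean −0.344, 2 of 6 lower, 4 when adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.0727 with an estimated correlation). The called members were CDH2, at least 1.01-fold lower, and VIM (−0.34), and VIM in HEK001 did not pass with median scaling or without any 1 HEK001 array other than knockdown replicate 3 (−0.36 to −0.31). A second VIM probe was lower by 0.53 in HEK001 (limma adjusted p = 0.00658 over all probes). Notch receptors, ligands and modifiers lost it as well (mean 0.152, 2 of 19 higher, none when adjusted over the list alone, camera adjusted p = 0.0379, adjusted p = 0.0877 with an estimated correlation).

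**Figure D2:**
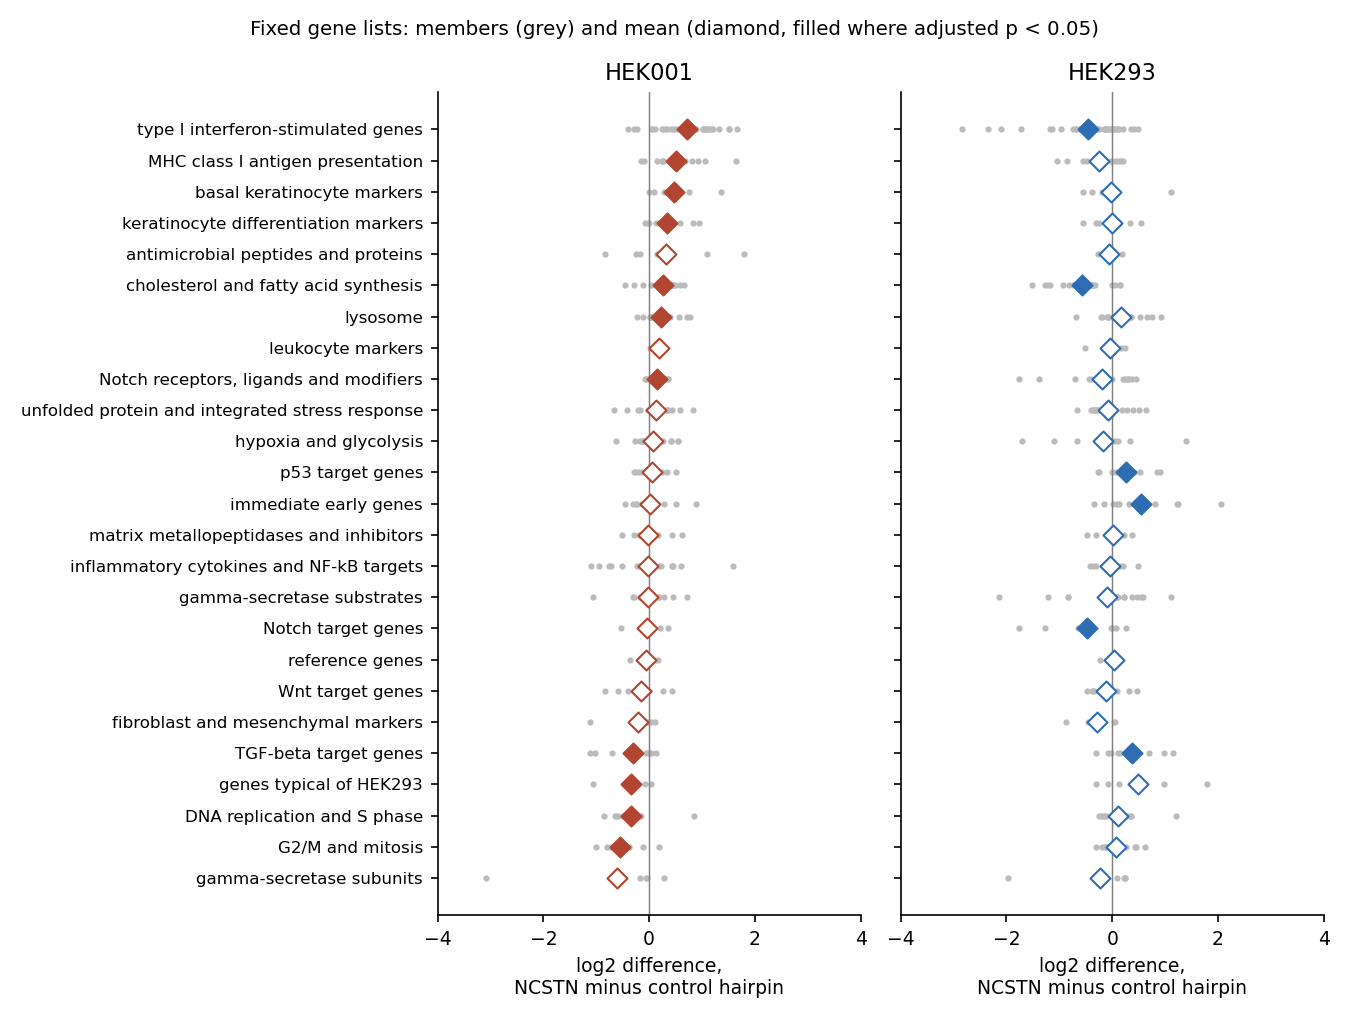
Log2 difference between the NCSTN and the control hairpin for the members (grey points) and the mean (diamond) of the 25 tested gene lists, in HEK001 (left) and HEK293 (right). Diamonds are filled where the camera adjusted p is under 0.05, which holds for 11 lists in HEK001 and 6 in HEK293; the interferon and cholesterol lists lie above 0 in HEK001 and below 0 in HEK293.

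HEK293 cells with the hairpin had higher levels of ANXA1, a phospholipid-binding protein gene, and of immediate early genes, and lower levels of interferon-stimulated and cholesterol synthesis genes. ANXA1 rose by 3.68 (SE 0.112), the kinase gene SGK1 by 2.40 (SE 0.11), VGF by 2.07 and EGR1 by 2.06. The control arrays were at or near background for PSG4, at least 5.16-fold higher, GADD45G, at least 4.16-fold, VCX3A, at least 4.06-fold, and GALR2, at least 3.73-fold. DHRS2, likewise kept only with all 3, was at least 3.51-fold higher and the transcription factor ETV5 at least 4.2-fold. A second ETV5 probe did not pass the threshold (0.42, adjusted p = 0.128 over all probes), and whether the VCX3A probe also reads related VCX genes was not analysed here. IGFBP5 fell by 2.78 (SE 0.138), HBQ1 by 2.44 (SE 0.101), TSC22D3 and UBE2L6 each by 2.36, and APIP by 2.20. IFITM1 was at least 6.75-fold lower, IFIT1 at least 3.93-fold, the urea cycle gene CPS1 at least 3.23-fold and CDH1, the E-cadherin gene, at least 3.2-fold. In all, 2868 of 11075 genes changed (limma, adjusted p under 0.05), 1374 higher and 1494 lower, and 256 of them by at least 2-fold, 94 higher and 162 lower.

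The interferon-stimulated genes fell in HEK293. Of the 42 measured, 27 were detected on all arrays of at least 1 arm, 19 were lower, 1 was higher and 22 did not pass the threshold (20 and 1 when adjusted over the list alone). The mean was −0.465 (camera adjusted p = 1.48e-05, adjusted p = 0.00524 with an estimated correlation). UBE2L6 fell by 2.36 (−1.08 for a second probe) and IFITM2 by 1.73, beside IFITM1 and IFIT1, where reading of related IFITM genes by these probes was not analysed here. Of MHC class I genes 4 of 15 were lower, among them TAP1 (−1.04) and PSME1 (−0.85), also when adjusted over the list alone, and the list did not pass (mean −0.252, camera adjusted p = 0.061). Of 20 cholesterol and fatty acid synthesis genes 13 were lower and none was higher (15 when adjusted over the list alone), with INSIG1 down by 1.51 and FADS1 by 1.26. Their mean was −0.567 (camera adjusted p = 5.28e-07, adjusted p = 0.00524 with an estimated correlation).

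Immediate early genes rose in HEK293, where 7 of 12 were higher, also when adjusted over the list alone (mean 0.538, camera adjusted p = 0.00178, adjusted p = 0.0377 with an estimated correlation). EGR1 rose by 2.06 and FOS was at least 1.74-fold higher. Calls lost with an estimated correlation were those for p53 targets (mean 0.267, 5 of 12 higher, also when adjusted over the list alone, TP53I3 0.91 and CDKN1A 0.84, camera adjusted p = 0.0359, adjusted p = 0.143) and TGF-beta targets (mean 0.365, 5 of 12 higher, 6 when adjusted over the list alone, ID1 1.15 and ID3 0.97, camera adjusted p = 0.00663, adjusted p = 0.156). G2/M genes had a mean of 0.0678 (camera adjusted p = 0.573), with BIRC5 higher by 0.63 (another BIRC5 probe 0.85) and TOP2A lower by 0.30, and replication genes a mean of 0.106 (camera adjusted p = 0.573), with RRM2 higher by 1.21.

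Notch receptors are substrates of gamma-secretase, and their targets were listed for that reason. In HEK293, 5 of 9 measured Notch targets were lower, also when adjusted over the list alone (mean −0.477, camera adjusted p = 0.0127, adjusted p = 0.0865 with an estimated correlation). MYC fell by 1.26 (SE 0.103), HES6 by 0.66 and HES4 by 0.50. NOTCH3, detected on 1 of the 3 knockdown arrays, was at least 3-fold lower. The ligand gene JAG2 fell by 1.38, while the list of receptors, ligands and modifiers did not pass (mean −0.19, camera adjusted p = 0.424). In HEK001 only HES6 was lower among the 9 targets (−0.53), and the list, of which 5 genes were detected, did not pass (mean −0.04, camera adjusted p = 0.734). Over the 5 detected genes the mean was −0.13, which did not pass either (camera adjusted p = 0.36). The difference between the lines did not pass for the target list (−0.433, camera adjusted p = 0.0799). Of 16 other gamma-secretase substrates, 1 was higher and 1 lower in HEK001 (mean −0.0265, camera adjusted p = 0.853), and 4 were higher and 4 lower in HEK293 (mean −0.092, camera adjusted p = 0.95), among them CXCL16 (−1.21).

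The 14 tested lists that did not pass in HEK001 had camera adjusted p-values between 0.0659 and 0.878, and the 19 in HEK293 between 0.061 and 0.962. The inflammatory list held 5 higher and 4 lower genes of 17 in HEK001 (mean −0.0255, CXCL2 at least 2-fold lower), and the antimicrobial list 3 higher and 1 lower of 8 (mean 0.314, S100A9 1.10). Neither CXCL2 nor S100A9 passed without background correction. In HEK001, p53 targets had a mean of 0.0526, with 1 of 12 higher and 0 lower. Immediate early genes had a mean of 0.0163 there, with 3 of 12 higher and 1 lower, so single members also changed in HEK001. HSPA5, an endoplasmic reticulum chaperone gene, rose by 0.82 and ATF3 fell by 0.66 in HEK001, while ATF3 rose by 0.63 and PSAT1 fell by 0.67 in HEK293. The unfolded protein list had means of 0.127 and −0.074. Hypoxia and glycolysis had means of 0.0683 and −0.177, with NDRG1 at 0.55 in HEK001 (NDRG1 in HEK001 did not pass without knockdown replicate 1, at 0.45) and −1.72 in HEK293, ADM at 1.39 in HEK293 and SLC2A3 at −1.09 in HEK293. Wnt targets had means of −0.15 and −0.117, with LEF1 at −0.83 and TNFRSF19 at −0.58 in HEK001. Metallopeptidases and their inhibitors had means of −0.0121 and 0.0104, with TIMP3 at 0.63 in HEK001. The list of gamma-secretase subunits had means of −0.614 and −0.238, which NCSTN itself carries, as the other 4 lay between −0.17 and 0.29. Reference genes had means of −0.0523 and 0.0246. Markers of other cells had means of −0.213 and −0.297 for fibroblasts and 0.178 and −0.0474 for leukocytes, of whose 4 measured genes 1 was detected in HEK001 and 2 in HEK293, and the 2 measured melanocyte genes were too few to test. In HEK293, the lysosome list had a mean of 0.175 with NEU1 at 0.91 and SQSTM1 at 0.76, and the HEK293-typical list 0.493 with VIM at 1.79. Few members of the keratinocyte and inflammatory lists were detected in HEK293, so means are given over the detected members. They were 0.369 for 2 of 10 basal markers, 0.016 for 5 of 14 differentiation markers, among them DSC2 at 0.55 (a second DSC2 probe at 0.10 did not pass), and −0.012 for 3 of 17 inflammatory genes. Of 8 antimicrobial genes 0 were detected in HEK293, and no mean is given. The mean and median had opposite signs for inflammatory and immediate early genes in HEK001 and for subunits, substrates and leukocyte markers in HEK293.

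The responses of the lines were compared directly. The difference between the effects passed the threshold for 2711 of 11075 genes, 1292 with the higher effect in HEK293 and 1419 with the lower (982 and 1383 with median scaling). It passed for 31 of the 42 interferon-stimulated genes, 30 of them lower in HEK293 (mean difference −1.18, camera adjusted p = 2.39e-18, adjusted p = 0.000118 with an estimated correlation). Only 27 of the 42 were detected on all arrays of at least 1 HEK293 arm, with a mean of −0.617 in HEK293. For genes such as MX2, the difference sets a rise in HEK001 against undetected values. IFI6 (1.20 in HEK001 and −1.18 in HEK293, with 1.82 and −1.28 for a second probe) and BTN3A2 (0.92 and −1.34, with 0.32 and −1.04 for a second probe) went from higher to lower, as did IFIT1 and IFITM1, higher by 1.52 and 1.09 in HEK001, while PER2 (−1.36 and 1.15) went the other way. For ETV5 the HEK001 difference was −0.94, and 0.10 for a second probe that did not pass, so that the opposite direction rests on 1 of 2 probes. UBE2L6 and HBQ1 rose by 0.86 and 0.59 in HEK001 and fell by 2.36 and 2.44 in HEK293. Genes called in both lines numbered 289 with the same sign and 318 with opposite signs, against 232.7 and 233.2 for independent lists and 243.4 and 247.1 for independent lists within deciles of expression. Across genes, which are not independent replicates, the effects correlated at Pearson's r −0.0229 and Spearman's rho −0.0384.

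Genes lower in both lines numbered 162, against 117.9 for independent lists (1-sided Fisher's exact p = 7.67e-06) and 123.3 for independent lists within deciles of expression (1-sided exact Mantel-Haenszel p = 7.96e-05). Higher in HEK001 and lower in HEK293 were 189, against 124.8 (exact p = 6.26e-10) and 128.7 within deciles (exact p = 6.51e-09). Genes higher in both numbered 127, against 114.8 (exact p = 0.112) and 120.1 within deciles (exact p = 0.254). Lower in HEK001 and higher in HEK293 were 129, against 108.4 (exact p = 0.0175), an excess that did not pass within deciles, against 118.4 (exact p = 0.146). These tests were not adjusted for each other, and those within deciles were added after the counts were seen. They treat genes as independent. Both contrasts also use the same estimate of each gene's spread, so genes of low spread tend to be called in both lines. Deciles of expression do not correct for that, and the p-values may overstate each excess. Besides NCSTN, 9 genes fell at least 2-fold in both lines. AUNIP fell by 1.48 and 1.52, APIP by 1.41 and 2.20, IL6ST, the shared receptor subunit of interleukin-6 type cytokines, by 1.27 and 1.28, and CPS1 by 1.16 in HEK001 and at least 3.23-fold in HEK293. ERH fell by 1.20 and 1.14, H2AZ1 by 1.43 and 1.13, the mitochondrial malic enzyme gene ME2 by 1.09 and 1.58, and ENOPH1 by 1.17 and 1.08. APIP and ENOPH1 encode enzymes of the methionine salvage pathway. MAPK13, the remaining gene of the 9, was named after its values were seen. The histone gene H2BC5 alone rose at least 2-fold in both lines (1.38 and 1.90, with 1.21 and 1.27 for a second probe).

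**Figure D3:**
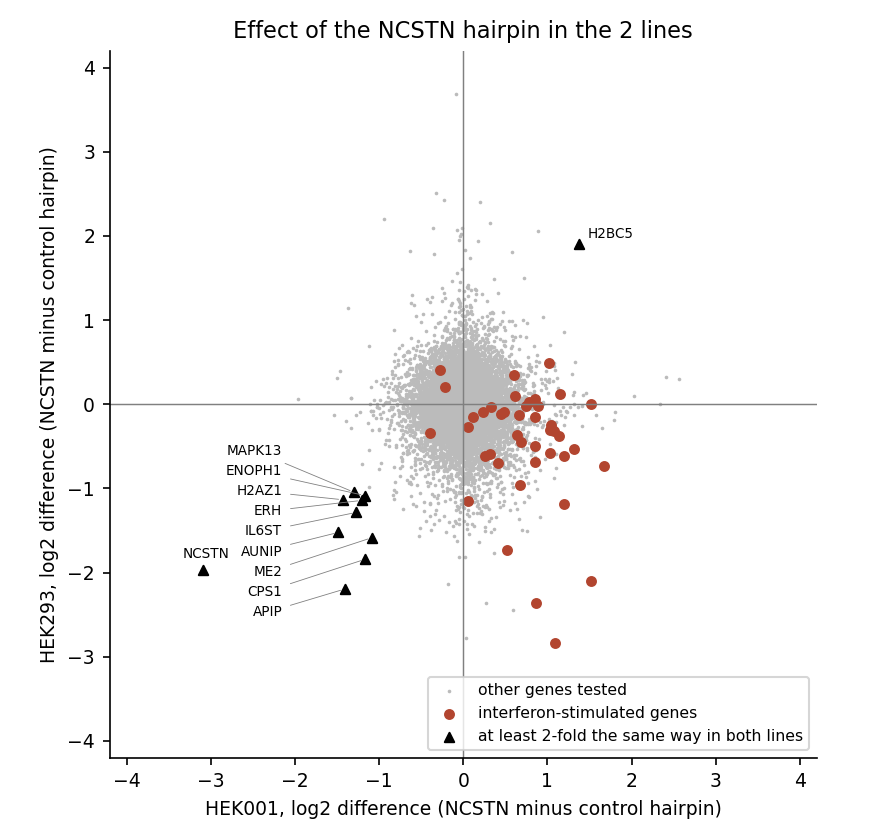
Log2 difference between the NCSTN and the control hairpin in HEK001 (horizontal) against HEK293 (vertical) for the 11075 genes, with interferon-stimulated genes in red and genes changed at least 2-fold the same way in both lines as black triangles. Of the triangles, 10 including NCSTN lie at lower left and 1, H2BC5, at upper right.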

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

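The tests of the interferon pattern, of the nearly uncorrelated effects and of the genes lowered in both lines, and the count of relabellings for genes changed the same way, were chosen after those results were seen. The counts of splits for the other results were planned.

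Effects of the NCSTN hairpin that differed between HEK293 and HEK001 by the test of the difference are given here, as the log2 effect in HEK293 minus that in HEK001. The difference passed for 2711 of 11075 genes. In 1 of 100 drawn relabellings of knockdown and control within the lines, the real one included, as many genes passed. The highest of the other relabellings gave 2363 genes, and it was the real assignment with the arms of 1 line exchanged. Apart from it the highest was 780, in relabellings that called 0 genes in at least 1 line. The relabellings argue against an absence of effects in both lines together and do not show an effect in each line. They do not test whether the effects differ, which rests on the test of the difference itself. For genes changed the same way, 289 in the real assignment, 2 of 100 relabellings gave as many. The other of these was the exchanged assignment, with 318, which turns opposite changes into shared ones, and the highest apart from it was 0. All these others called 0 genes in at least 1 line and had to give 0, so the count does not show an overlap beyond chance. Nor does it show an effect in each line, as a line has only 10 splits. For an overlap beyond chance the counts expected of independent lists apply, 243.4 within deciles of expression. Opposite changes in the real assignment, 318 against 247.1 within deciles, exceeded theirs as well. The estimate of each gene's spread that the lines share may raise both counts. For the effects within a line, the 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 1799 genes in HEK001 and the highest other split 0, in HEK293 2868 and 1, and between the control lines 8046 and 0. In each of these 3 cases, only 1 split, the real one, gave as many.

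Of 25 tested lists, 11 differed between the lines, 7 of them also with an estimated correlation. The effect in HEK293 was lower for interferon-stimulated genes (−1.18), cholesterol and fatty acid synthesis (−0.828), MHC class I presentation (−0.759), basal markers (−0.49), Notch receptors, ligands and modifiers (−0.342) and differentiation markers (−0.333). It was higher for genes typical of HEK293 (0.837), TGF-beta targets (0.673), G2/M and mitosis (0.624), immediate early genes (0.521) and DNA replication and S phase (0.457). Only 2 of 10 basal markers (mean 0.369) and 5 of 14 differentiation markers (mean 0.016) were detected in HEK293, so these differences largely set changes in HEK001 against undetected values. Of the 42 interferon-stimulated genes 27 were detected in HEK293, so this holds for part of that list. The 4 calls lost with an estimated correlation were those for Notch receptors, basal markers, differentiation markers and replication.

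Of 114 named genes, 94 differed between the lines, with adjusted p-values up to 0.0497, and 60 of them were detected in every group, on at least 1 array. The naming rule picks genes for large effects or differences in these same contrasts, and some of the 114 belong to families chosen after seeing the data. That selection raises the share of named genes that differed, so it is no separate result. Over all genes the share was 24.5%. Where an arm was detected on only some arrays, the fitted difference includes values at background. Among these 60, the effect was higher in HEK293 for ANXA1 (3.78), PER2 (2.51), SGK1 (2.20), VGF (2.15), VIM (2.13), MNS1 (1.86), RRM2 (1.83), CCN2 (1.82), H1-2 (1.47), TMEM156 (1.41), ADM (1.34), BIRC5 (1.29), ATF3 (1.29), CRY2 (1.26), ID1 (1.20), EGR1 (1.17), LEF1 (1.14), NCSTN (1.12) and TYMS (1.12). Smaller differences of this sign were those of PMEPA1 (1.00), CCNA2 (0.97), DUSP6 (0.95), ID3 (0.94), SQSTM1 (0.87), TP53I3 (0.82), CDKN1A (0.74), TOP2A (0.70), NEU1 (0.66), DSC2 (0.62) and H2BC5 (0.52). The effect was lower in HEK293 for IFITM1 (−3.93), IFIT1 (−3.62), UBE2L6 (−3.22), HBQ1 (−3.03), TSC22D3 (−2.64), IFI6 (−2.38), FGFR3 (−2.27), NDRG1 (−2.27), IFITM2 (−2.26), BTN3A2 (−2.25), IGFBP2 (−1.99), HLA-B (−1.93), ISG15 (−1.85), INSIG1 (−1.84), JAG2 (−1.69), PSME1 (−1.54), MVD (−1.51), MYC (−1.48) and TAP1 (−1.48). Smaller differences of this sign were those of CXCL16 (−1.37), HLA-C (−1.34), DBP (−1.31), LSS (−1.31), GAA (−0.99), HSPA5 (−0.85), FADS1 (−0.80), APIP (−0.79), CPS1 (−0.68), PSAT1 (−0.65) and ME2 (−0.50). The differences of FGFR3 and DSC2 each rest on 1 of 2 probes. Their second probes passed in neither line and differed the other way, with −0.27 in HEK001 and −0.14 in HEK293 for FGFR3 and 0.41 and 0.10 for DSC2.

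For genes at background in 1 line the difference compares a change with undetected values. The 15 not detected in HEK293 were CLCA2 (−2.34), CXCL14 (−2.09), DIRC3 (−1.93), S100A8 (−1.89), IL33 (−1.71), FOLR3 (−1.58), MX2 (−1.51), KRT15 (−1.40), S100A9 (−1.24), DST (−0.77), DSG3 (−0.72), NTM (1.20), CXCL2 (1.30), PER3 (1.41) and KRT80 (2.02). The 9 not detected in HEK001 were IGFBP5 (−2.81), NOTCH3 (−2.14), KRTDAP (−0.75), H4C8 (1.81), VCX3A (1.83), GADD45G (2.10), GALR2 (2.45), DHRS2 (2.66) and PSG4 (2.83). In 10 genes 1 arm was not detected: SAMD9 (−2.41), CDH1 (−1.96), SPRR1B (−1.19), ETV4 (0.51), SPRY4 (0.71), CDC6 (0.85), CDH2 (0.98), FOS (1.32), FAM43B (1.81) and ETV5 (3.14).

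Interferon-stimulated genes were higher with the NCSTN hairpin in HEK001 and lower in HEK293. With each line normalized and fitted alone, the list means were 0.758 in HEK001 and −0.559 in HEK293, a difference of −1.32, which argues against joint normalization as the source. NCSTN was lower by −1.97 on the HEK293 arrays labelled with its hairpin, which argues against exchanged arms in that line. An interferon response to 1 of the lentiviral constructs, the NCSTN or the control hairpin, stays open because the design has 1 NCSTN hairpin and no uninfected cells. A difference between the lines in the response to nicastrin loss also stays open and was not tested. It cannot be told apart from the labelled puromycin value or the depth of knockdown, which differed between the lines too.

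The effects of the lines were nearly uncorrelated across genes (r −0.0229). The count of 289 genes changed the same way was above that of independent lists (232.7). So was the count of 318 genes changed in opposite ways (233.2), and the shared estimate of each gene's spread may raise both. Among 7623 genes detected on all 12 arrays, the effects correlated across genes at r −0.012, which argues against genes below background in 1 line as the reason. After removal of the estimated noise variance (20.5% of the variance in HEK001 and 13.5% in HEK293) the correlation was −0.0276, and −0.0353 to −0.0204 with each array left out in turn. Noise of that size changed the correlation only slightly. The correction rescales the same covariance and could not turn a correlation just below 0 positive, so it is no test of noise hiding a shared response. Differences in biology between the lines stay open and were not tested. The labelled puromycin value and the depth of knockdown also differed between the lines, and the design cannot tell these apart.

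Besides NCSTN, 9 genes were lower by at least 2-fold in both lines and 1 was higher, against 0.582 and 0.577 for independent lists. Off-target repression by the hairpin that both lines share may lower such genes. Lowered outnumbered raised genes with an exact binomial p of 0.0215 at 2-fold, a limit chosen after the counts were seen. At any fold the exact binomial p was 0.0771 (161 against 127). Regulation by the loss of nicastrin could give the same excess, so this test cannot tell it from off-target repression, whatever its p. The planned test of genes matching the seed of the hairpin was not run. Both explanations stay open, since 1 NCSTN hairpin was used and a second would be needed to tell them apart.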

How the results depend on the processing

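The settings that leave out the 2 arrays of lowest weight, or list members not detected in the line, were chosen after seeing the data. All others were planned, and a slide block was not run because the arrays could not be assigned to slides from their names.

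NCSTN stayed lower in every setting run, between −3.29 and −2.75 in HEK001 and between −2.05 and −1.82 in HEK293, and interferon-stimulated genes stayed higher in HEK001 (0.633 to 0.771) and lower in HEK293 (−0.703 to −0.337), each past its threshold. Counts ranged from 1353 to 2252 in HEK001, 2310 to 3729 in HEK293, 2123 to 3523 for the difference and 219 to 374 for genes changed the same way, arrays left out singly aside. The upper ends 2252, 3729 and 3523 count probes, from the setting with every probe on its own. Counted as genes, the highest were 2237 in HEK001 (array weights), and 3189 in HEK293 and 3116 for the difference (another offset). The share of changed genes that were higher in HEK001, 51.4%, was 48% without background correction, 49.4% with an intensity trend and 58.1% with median scaling. For the difference it was 47.7%, and 41.5% with median scaling. With every probe on its own, 12336 differed between the control lines, where more features were tested. With an estimated correlation 6 lists passed in HEK001 and 3 in HEK293, where the Notch targets (−0.477) had an adjusted p of 0.0865 (0.00333 to 0.0865 over the settings with camera). With fry, which does not compare a list with other genes, 14 passed in HEK293.

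With a replicate block the counts were 1454 in HEK001, 2569 in HEK293, 2421 for the difference, 6850 between the control lines and 219 for genes changed the same way. Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated across genes at −0.0472 to 0.0719. Without the 2 arrays of lowest weight the counts were 1542, 2518, 2379, 7843 and 239.

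With each array left out in turn, the count was 1146 (without HEK001 control replicate 3) to 1863 in HEK001, 2230 to 3000 in HEK293, 2249 to 2539 for the difference, 7596 to 8090 between the control lines and 194 to 270 for genes changed the same way. These fits have fewer arrays, and the cause of the count of 1146 was not tested.

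Signs reversed for values that passed in neither case. H4C8 was not detected in HEK001 and PER3 was not detected in HEK293, so their values here lie at background and state no change. Without background correction, Notch targets in HEK001 had a mean of 0.0737 (adjusted p = 0.917, 0.36 to 0.917 over the settings with camera), H4C8 in HEK001 −0.083 and PER3 in HEK293 −0.37. With the authors' values H4C8 was −0.010 and PER3 −0.013, and with array weights H4C8 was −0.081. Without the 2 arrays of lowest weight DUSP6 in HEK001 was 0.0035, H4C8 −0.15 and PER3 −0.0062. With arrays left out singly, APH1A in HEK001 ranged from −0.11 to 0.015, DUSP6 in HEK001 from −0.30 to 0.0041, H4C8 in HEK001 from −0.15 to 0.12 and PER3 in HEK293 from −0.11 to 0.27. The cause was not tested.

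Of 145 called values of named genes, 22 lost the call in some setting, 19 of them without background correction, and 0 reversed. With each line normalized and fitted alone, 1 of 141 named values lost its call, and the other 140 kept their sign and their call or lack of one. The cause of the losses without background correction was not tested. Signal over background limits what the arrays show, as changes in probes not detected cannot be measured. Probes removed by a filter gave no value: IL33 in HEK001 and DHRS2 in HEK293 without any 1 of the knockdown arrays of that line, and CDH2 and SLC2A3 in HEK001, SPRY4 and CDC6 in HEK293, H4C8 and NOTCH3 in HEK001 and PER3 in HEK293 with the stricter filter or each line alone. With every probe on its own, lists were not tested.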

Other observations

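The 3 gene families here were chosen after seeing the data, and no explanation was tested for them.

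Of 10 measured genes that respond to ERK signalling and feed back on it, picked after ETV5 had been seen and not tested as a group, 7 were higher, 0 lower and 3 not past the threshold in HEK293 (median log2 difference 0.66), while in HEK001 1 was higher and 2 were lower (median 0.029), and the effects of 6 differed between the lines. In HEK293, DUSP6, a phosphatase gene that acts on ERK, was at least 1.75-fold higher, ETV4 at least 1.18-fold and SPRY4 at least 1.05-fold, beside ETV5. The call of ETV4 in HEK001 (0.39) was lost in most settings. DUSP6 is also on the list of immediate early genes. The HEK293 median was between 0.422 and 0.778 under the 5 scalings tried, under which the median of all genes stayed within 0.0344 of 0.

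Of 25 clustered histone genes measured, 13 were higher and 1 was lower in HEK293 (median 0.613, between 0.329 and 0.915 under the scalings), and 5 were higher and 2 lower in HEK001 (median 0.102). The effects of 15 differed between the lines. H4C8 was higher by 1.83 and the linker histone gene H1-2 by 1.26 in HEK293. Whether these probes also read related histone genes was not analysed here.

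Of 9 circadian clock genes measured, 4 were lower and 2 higher in HEK001 (median −0.362), and 2 were lower and 3 higher in HEK293 (median 0.189). The effects of 4 differed between the lines. PER3 was at least 1.85-fold lower in HEK001, CRY2 was −0.60 in HEK001 and at least 1.52-fold higher in HEK293, and DBP was at least 2.18-fold lower in HEK293. The call of PER3 in HEK001 was lost without background correction, and that of CRY2 in HEK001 without HEK001 control replicate 3 (−0.53) or HEK001 knockdown replicate 3 (−0.51).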
